A study of Homo sapiens with 6 samples.

How the data were processed

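RNA was extracted from NCI-H146 cells with a column kit after 9 days in 2.5 µM valemetostat or vehicle, with the drug renewed every 3 days, per the labels' protocols. Stranded total RNA libraries were made from 500 ng of RNA and sequenced as paired-end reads of 100 bp, per the labels. Reads were processed with Trim Galore, STAR and Salmon on the hg38 build, per the submitters' processing notes. Tool versions, the annotation release and the strand setting of the counting are not given in the sources used here. The authors deposited expected counts per gene, which Salmon estimates by dividing reads among transcripts, for 62703 genes in 6 columns, and between 12.9 and 14.4% of the values of a library had decimals. Reads shared by overlapping genes or near-identical copies are divided by this estimate, so values of paralogs, readthrough transcripts and overlapping or antisense genes are uncertain. Total RNA libraries also hold unspliced and noncoding transcripts.

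The 3 vehicle and 3 valemetostat libraries were taken as replicates of their groups, per the labels. Pearson correlations of log2 CPM and a chi-square comparison of counts found no pair of libraries that agreed within sampling noise. Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with its defaults (minimum count 10, minimum total count 15), which left 19403 genes and removed 43300. Libraries were scaled by TMM, and groups were compared with edgeR's quasi-likelihood test with robust dispersion, two-sided, with group as the only term and Benjamini-Hochberg adjustment at 0.05. CPM values use the TMM-scaled library sizes. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Counts were simulated for the same 19403 genes in this comparison, with 200 genes changed up or down at random from their mean over all libraries. The test called 49.3% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 90.9% of those changed 4-fold in the right direction, and 6.54% of 153 calls were unchanged genes. The data had 7636 called genes, many silent in vehicle, while no simulated gene started silent. These rates therefore need not hold for the real comparison.

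A gene with no count in a group was given a lower bound of its fold against 3 counts over that group, and a gene with 1 to 3 vehicle counts a ratio with an exact 95% counting interval. Both cover counting error only. Genes were tested in 22 lists with camera in limma on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01 and adjustment over the 22 lists. Counts and medians of a list cover its tested members only, and a gene silent in vehicle passes the filter on low counts only where it has counts after valemetostat, which favours risen members in the counts of lists low in vehicle. No camera call at an adjusted p under 0.05 held with an estimated correlation. The estimate was -0.0488 for chemokine, -0.0157 for immune ligand and 0.00713 for epithelial genes, and 0.0445 to 0.362 for the other lists called. The first 3 lie below the preset value, so a higher correlation within these lists does not account for the loss of their calls. Fry was run beside camera, and its directional and mixed values are given with the alternatives where they lay on the other side of the threshold from camera or had another direction. Gene positions and types came from GENCODE release 29 on GRCh38, matched by Ensembl identifier without its version for 18502 of the 19403 tested genes. In the file, 1486 symbols occurred more than once, so list members were followed by identifier.

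Named genes followed a rule set before the data were examined. The rule took the 6 genes with the largest rise and the 6 with the largest fall among those called, with a mean of at least 5 CPM in the higher group, no overlap between groups and a gene symbol. It took from each list the 2 called members with the largest change and a mean of at least 1 CPM in the higher group, or, where fewer passed, the members with the highest expression. Another 16 genes were fixed in advance, which made 71 in all. Of these 16, EZH2, EZH1, SLFN11, B2M, HLA-B, HLA-C, NLRC5, CIITA, CD274, STING1, INSM1, REST and AXL are given, and results of the others are not reported here. Other list members were named as examples after their values were seen.

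Alternatives covered DESeq2 size factors, library size only, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2, limma-voom, dispersion without the robust option, counts without rounding, the replicate number as a block, each library left out in turn, an adjusted p under 0.01, edgeR's glmTreat against a fold of 1.5, an estimated correlation, fry and a prior count of 0.5. Fits without the mitochondrially encoded genes and with protein-coding genes only were added after seeing the data, as were counts of gene families without each library and their comparison within deciles of vehicle expression.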

Results

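Gene expression was measured by RNA sequencing in NCI-H146, an established small cell lung cancer line that grows with a neuroendocrine character. Cells were kept for 9 days in 2.5 µM valemetostat or in DMSO vehicle, and 3 libraries were made per group. Valemetostat inhibits EZH1 and EZH2, the alternative catalytic subunits of Polycomb repressive complex 2 (PRC2), which places a silencing methyl mark on histones. The 3 vehicle libraries held about 35704100, 34347100 and 44945600 expected counts, and the 3 valemetostat libraries 35913800, 22768000 and 37730000. Expression is given as CPM, the count scaled to library size, mean ± SD with n = 3, and log2 fold changes are valemetostat over vehicle. The comparison addressed which genes change when EZH1 and EZH2 are blocked. The study's title places these changes in the context of genome folding and of an immunogenic phenotype.

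Valemetostat raised a large set of genes that were silent or nearly silent in vehicle. The genes that fell started from higher levels and mostly moved less, a contrast that selection by fold change partly sets in advance. Most of the tested genes of antigen presentation, of the HOX clusters and other developmental regulators, and of a list of non-neuroendocrine and Notch-YAP genes rose. INSM1, a neuroendocrine transcription factor, was not called, at 527 ± 10.2 CPM in vehicle and 552 ± 111 CPM after valemetostat. Lists of proliferation genes and of cohesin and other genome folding genes had medians below 0, with 14 of 40 and 15 of 34 members lower. Of 19403 genes tested with edgeR's quasi-likelihood test, 7636 changed at a Benjamini-Hochberg adjusted p under 0.05, 4344 higher and 3292 lower.

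Changes of at least 2-fold were mostly upward, in 2468 genes against 488 downward. The imbalance widened with size, to 1636 genes higher and 70 lower at 4-fold, and 867 higher and 4 lower at 16-fold. Median vehicle expression was 0.244 CPM for the genes higher and 2.37 CPM for the genes lower by at least 2-fold. With smaller changes included it was 1.75 CPM for all genes that rose, 41.6 CPM for those that fell and 15.3 CPM for those not called. Without a filter on low counts these last medians were 0.508, 40.0 and 0.148 CPM, so that the genes not called lay below those that rose. With the filter, the value for the genes that rose was 0.740 CPM without vehicle replicate 3 and between 1.04 and 1.14 CPM without any other library except valemetostat replicate 3. Among the genes higher by at least 2-fold, 1840 (74.6%) had a vehicle mean under 1 CPM, and 227 had no count in any vehicle library, while 148 of the 488 lower by at least 2-fold had a vehicle mean under 1 CPM. Part of this contrast follows from the selection, since vehicle expression is the base of the fold. A gene near 0 cannot be seen to fall far, small changes are called more easily at high counts, and the filter keeps genes silent in vehicle only where they have counts after valemetostat. Protein-coding genes made up 1995 of the 2468 risen genes but 238 of the 488 fallen genes, and long noncoding genes 298 and 158. More genes carried a count after valemetostat, 28254 ± 804 against 26301 ± 650 per library, although an exact two-sided permutation test of 3 against 3 libraries gave p = 0.1, the smallest value it can reach. All 3 libraries of a group lay above all 3 of the other for 10071 tested genes, where chance gives 10%. The labels state biological replicates without saying whether they were separate cultures. The p-values set the group difference against the spread between these libraries, some of which may be technical.

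The 6 largest rises came from genes with at most 1 count in vehicle. CFC1, a co-receptor of Nodal signalling (ENSG00000136698.10, chromosome 2, 130592168 to 130599575, GRCh38), had no vehicle count and reached 11.9 ± 1.25 CPM, at least 449-fold higher (edgeR adjusted p = 9.01e-08), although it has a near-identical copy, CFC1B, with which reads can be exchanged. ADCYAP1R1, the receptor of the neuropeptide PACAP (ENSG00000078549.16, chromosome 7, 31052461 to 31111479), reached 6.65 ± 0.941 CPM from no count, at least 246-fold higher. LRRC4B, a synaptic adhesion protein (ENSG00000131409.13, chromosome 19, 50516892 to 50568045), was at least 241-fold higher at 6.43 ± 1.65 CPM. CD70, the ligand of the T cell co-stimulatory receptor CD27 (ENSG00000125726.11, chromosome 19, 6583183 to 6604103), was at least 204-fold higher at 5.30 ± 1.40 CPM (edgeR adjusted p = 1.67e-06). GPRIN2 (ENSG00000204175.6, chromosome 10, 46549044 to 46555530) was at least 185-fold higher at 5.0 ± 1.0 CPM. GPRC5C, an orphan G protein-coupled receptor (ENSG00000170412.18, chromosome 17, 74424851 to 74451653), went from 1 vehicle count to 12.2 ± 2.20 CPM, a ratio of 1355 with a 95% counting interval of 243 to 53574. Bounds were set against 3 counts over the vehicle group, and bounds and intervals cover counting error only.

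The 6 largest falls involved several noncoding or ambiguous transcripts. PURPL, a long noncoding RNA known as a regulator of p53 (ENSG00000250337.9, chromosome 5, 27472292 to 27496401), fell from 8.46 ± 1.97 to 1.16 ± 0.193 CPM, a log2 fold change of -2.87 (edgeR adjusted p = 2.62e-06). LAMA2, a laminin chain of basement membranes (ENSG00000196569.14, chromosome 6, 128883141 to 129516569), fell from 8.72 ± 1.37 to 1.59 ± 0.294 CPM. GCNT3, a mucin-type glycosyltransferase (ENSG00000140297.13, chromosome 15, 59594875 to 59640239), went from 5.30 ± 1.62 to 0.976 ± 0.149 CPM, and the long noncoding LINC02008 from 5.88 ± 1.05 to 1.01 ± 0.188 CPM. KLRC2, a natural killer cell receptor gene, went from 14.0 ± 3.22 to 2.05 ± 0.371 CPM, but it shares exons with KLRC1 in the annotation. The readthrough transcript BLOC1S5-TXNDC5 went from 569 counts to 0, at least 162-fold lower against 3 counts over the valemetostat group (edgeR adjusted p = 0.00219, and 0.0547 without a filter on low counts). It overlaps BLOC1S5 and TXNDC5, so its counts depend on how reads were divided among these genes.

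The drug targets themselves did not pass the test. EZH2 (ENSG00000106462.12, chromosome 7, 148807383 to 148884321) measured 197 ± 20.9 CPM in vehicle and 175 ± 22.3 CPM after valemetostat (log2 fold change -0.18, edgeR adjusted p = 0.236). EZH1 measured 34 ± 5.6 and 32 ± 8.0 CPM (edgeR adjusted p = 0.692). Among 12 PRC2 subunits, 2 rose and 2 fell, counts that were also 2 and 2 adjusted over the list alone. EPOP, an accessory subunit, rose from 19.1 ± 0.523 to 50.9 ± 2.78 CPM (log2 fold change 1.41) and JARID2 by 0.22, while the core subunit SUZ12 fell by 0.37 and PHF19 fell by 0.26 on the log2 scale. The list had a median log2 fold change of -0.07 and a mean of 0.05, and the camera test against all other genes gave a downward direction with adjusted p = 0.656. With any library left out 1 member was higher, and 1 was lower without vehicle replicate 3 or valemetostat replicate 2.

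Genes of MHC class I antigen presentation were mostly higher. Of 24 tested, 14 rose and 2 fell, or 17 and 2 adjusted over the list alone (median log2 fold change 0.48, camera adjusted p = 1.14e-04). With an estimated correlation the set test gave adjusted p = 0.223. The immunoproteasome subunit PSMB8 (chromosome 6, 32840717 to 32844703) rose from 0.129 ± 0.0242 to 11.5 ± 0.376 CPM (log2 fold change 6.42, edgeR adjusted p = 8.58e-09), and it overlaps PSMB8-AS1 and PSMB9 on the opposite strand. The peptide transporter genes TAP1 and TAP2 rose by 5.82 and 4.83 on the log2 scale, and the nonclassical genes HLA-E, HLA-G and HLA-F by 4.97, 4.99 and 3.01. HLA-B (ENSG00000234745.14, chromosome 6, 31269491 to 31357188) rose from 30.3 ± 2.15 to 175 ± 20.9 CPM and HLA-C from 56.5 ± 0.874 to 126 ± 8.05 CPM (edgeR adjusted p = 4.32e-08 and 1.12e-06). B2M, the invariant light chain, measured 103 ± 12.9 and 115 ± 10.4 CPM and did not pass (edgeR adjusted p = 0.284). NLRC5, the transactivator of class I genes, rose from 0.592 ± 0.160 to 3.55 ± 0.747 CPM. ERAP1 and CANX, a trimming peptidase and a chaperone, fell by 0.28 and by 0.26 on the log2 scale, but neither was called without vehicle replicate 1 or 3 or valemetostat replicate 1 or 2, and 1 was called without valemetostat replicate 3. Similar HLA sequences can exchange reads, so values of single HLA genes are uncertain.

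MHC class II genes moved the same way from a lower base. Of 12 tested among 19, 9 rose and 1 fell, the same counts adjusted over the list alone (median log2 fold change 1.33, camera adjusted p = 0.00310, and adjusted p = 0.309 with an estimated correlation). HLA-DPB1 went from 1 vehicle count to 3.10 ± 0.359 CPM, a ratio of 354 with an interval of 63.0 to 14018, and HLA-DPA1, which overlaps it on the opposite strand, rose by 5.17 on the log2 scale to 1.39 ± 0.339 CPM. CIITA, the master regulator of class II transcription, rose from 0.0386 ± 0.0444 to 0.936 ± 0.201 CPM (edgeR adjusted p = 1.33e-04). RFXAP, a DNA-binding partner of CIITA, was the member that fell, by 0.28 on the log2 scale, and it was not called when any library was left out. Over the region from 29 to 34 Mb of chromosome 6, which holds both classes, 51 of 140 tested genes rose, 35 of them by at least 2-fold, and 2 fell.

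**Figure D1:**
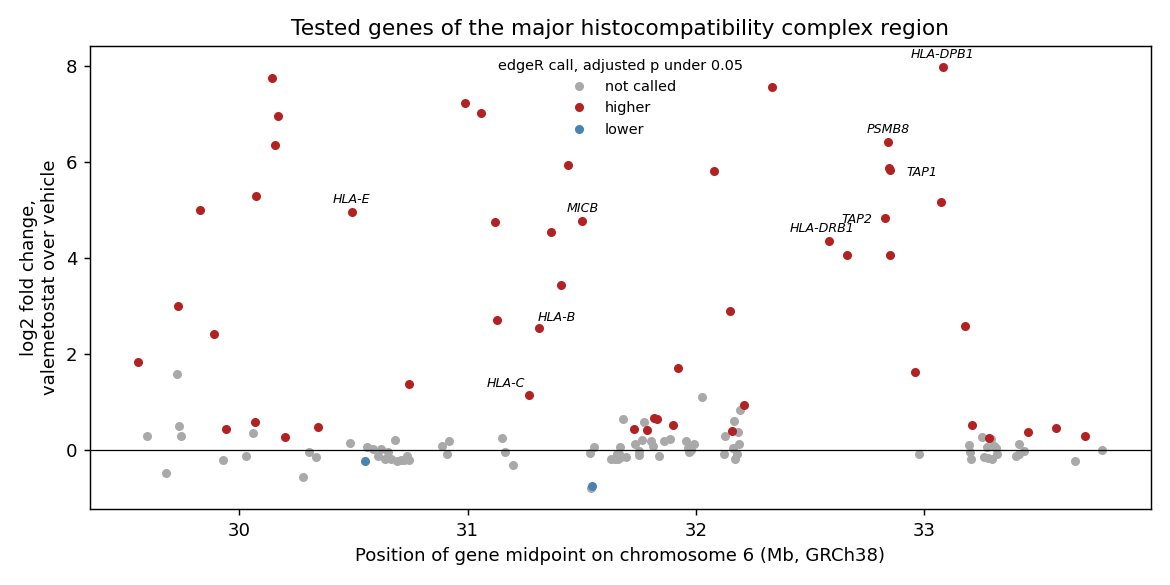
Log2 fold change of valemetostat over vehicle (y axis) against gene midpoint on chromosome 6 in Mb (x axis) for the 140 tested genes with a symbol between 29 and 34 Mb, each point a gene, coloured by its edgeR call. The 51 genes called higher include PSMB8, TAP1 and TAP2 close to each other near 33 Mb.

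Other immune lists held both risen and fallen genes. Of 48 chemokine and cytokine genes 18 had enough counts to be tested, of which 10 rose and 3 fell, or 11 and 3 adjusted over the list alone (median log2 fold change 1.33, camera adjusted p = 0.00884, and adjusted p = 0.223 with an estimated correlation and 0.235 with a filter of at least 1 CPM in 3 libraries). CXCL16, a ligand of the T cell receptor CXCR6, rose from 0.46 ± 0.12 to 11 ± 0.14 CPM, and CXCL14 from 31.0 ± 4.81 to 139 ± 25.5 CPM (edgeR adjusted p = 4.64e-08 and 2.50e-06). CXCL8, a neutrophil attractant, and TNFSF13B, a B cell survival factor, fell by 1.29 and by 1.23 on the log2 scale. Of 32 immune ligands and checkpoint genes 15 rose and 5 fell, or 16 and 5 adjusted over the list alone (median log2 fold change 0.34, camera adjusted p = 0.0224, and adjusted p = 0.223 with an estimated correlation). Besides CD70, TNFSF9, the ligand of a T cell co-stimulatory receptor, went from 1 count to 3.58 ± 0.473 CPM, a ratio of 401 with an interval of 71.4 to 15868. MICB, a ligand of the activating receptor NKG2D, rose from 0.78 ± 0.23 to 22 ± 1.5 CPM, while the natural killer cell ligands ULBP1 and NCR3LG1 fell, with log2 fold changes of -0.47 and -0.83 (edgeR adjusted p = 6.03e-04 and 0.00131). CD274, which encodes PD-L1, rose from 0.278 ± 0.0939 to 1.18 ± 0.381 CPM (edgeR adjusted p = 0.00102).

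Interferon-stimulated genes split. Of 44 tested among 58, 21 rose and 9 fell, or 21 and 11 adjusted over the list alone, with a median log2 fold change of 0.20 and no difference from other genes by camera (adjusted p = 0.380). Fry, which asks only whether members move on balance one way, gave an upward direction with adjusted p = 5.57e-05. XAF1, GBP5, HERC5, IFITM3, ISG15 and LY6E rose by 4.33, 2.99, 2.95, 2.24, 2.10 and 1.91 on the log2 scale. The antiviral genes IFIT1, IFIT2 and RSAD2 fell, with log2 fold changes of -1.14, -1.24 and -0.84 (edgeR adjusted p = 0.00118, 0.00152 and 0.00463). Among 16 nucleic acid sensing genes 0 rose and 3 fell with edgeR, or 0 and 2 adjusted over the list alone (median log2 fold change 0.18, camera adjusted p = 0.921). The count of risen members was 3 at an unadjusted p under 0.05, 0 with DESeq2 and 1 with limma-voom, and 1 without vehicle replicate 3 or valemetostat replicate 3. The RNA sensors RIGI and IFIH1 fell by 0.55 and by 0.39 on the log2 scale, and the kinase gene TBK1 fell by 0.32. IFIH1 was close to the threshold (edgeR adjusted p = 0.0475), and its call was lost in 10 of the alternative settings, including each library left out. STING1, the adaptor of cytosolic DNA sensing, had 10 counts in vehicle and 12 after valemetostat and was too low to be tested.

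Among developmental regulators, the classical targets of Polycomb silencing, most tested members rose. Their set tests compare them with all other tested genes, not with genes of the same vehicle expression. Of 34 HOX genes 18 rose and 2 fell, or 19 and 2 adjusted over the list alone (median log2 fold change 0.46, camera adjusted p = 1.24e-04, and adjusted p = 0.223 with an estimated correlation). Setting the 7 members at 0 in vehicle to their bounds left the median unaltered, and it could not move, since these bounds lie above it. HOXC4 and HOXC9 had no vehicle count and were at least 77.7-fold and at least 60.1-fold higher, both overlapping HOXC6 in the annotation, and HOXB9 rose from 19.2 ± 3.12 to 93.5 ± 4.81 CPM. HOXA6 and HOXD3 fell by 1.16 and by 0.58 on the log2 scale. Of these, 1 was lost without vehicle replicate 3, valemetostat replicate 1 or valemetostat replicate 2. Of 51 other developmental transcription factors 33 rose and 6 fell, or 35 and 7 adjusted over the list alone (median log2 fold change 0.86, camera adjusted p = 6.10e-06, and adjusted p = 0.326 with an estimated correlation). The same holds for this median with the 4 members at 0 in vehicle at their bounds. TBX5, a heart and limb regulator, was at least 66.8-fold higher. EN2, a regulator of hindbrain patterning, went from 2 counts to 6.98 ± 1.33 CPM, a ratio of 398 with an interval of 110 to 3290. GATA2 rose from 7.80 ± 0.906 to 40.0 ± 2.55 CPM, while PAX6, an eye and forebrain regulator, fell from 30.9 ± 1.64 to 15.3 ± 1.38 CPM (edgeR adjusted p = 1.02e-07 and 2.09e-05).

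More neuroendocrine genes fell than rose. Among 45 tested, 9 rose and 14 fell, or 9 and 15 adjusted over the list alone (median log2 fold change -0.18, mean -0.02, camera adjusted p = 0.0451, and adjusted p = 0.401 with an estimated correlation). The set test gave 0.116 with a filter of at least 1 CPM in 3 libraries, 0.0517 without vehicle replicate 1, 0.0563 without valemetostat replicate 1 and 0.0631 without valemetostat replicate 2, and 5 members rose without vehicle replicate 3. INSM1 did not pass (edgeR adjusted p = 0.707). The members that fell included RIMS2, SCG2 and TAGLN3, genes of vesicle release and neuronal structure, by log2 fold changes of -0.71, -0.69 and -0.68. Rising members included NKX2-1, a lung lineage factor, from 0.106 ± 0.0868 to 3.98 ± 0.257 CPM with an antisense gene over it, GRP, a neuropeptide gene, from 6.41 ± 1.15 to 16.7 ± 2.32 CPM, and DLL3, an inhibitory Notch ligand, by 0.57 in log2 units. REST, a repressor of neuronal genes, rose from 0.248 ± 0.171 to 3.72 ± 0.0952 CPM (edgeR adjusted p = 1.27e-05).

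A list of non-neuroendocrine and Notch-YAP genes joins markers of the non-neuroendocrine state with genes of the 2 pathways. Its tested members rose in 27 of 40 cases and fell in 0 by edgeR, or 29 and 1 adjusted over the list alone (median log2 fold change 1.22, camera adjusted p = 2.32e-07, and adjusted p = 0.374 with an estimated correlation). The count of fallen members was 1 at an unadjusted p under 0.05, and 0 with DESeq2 and with limma-voom. Vehicle replicate 3 stood apart, with 4 tested members at least 4-fold above both other vehicle libraries. Of the members too low to be tested, it held 70 of 70 vehicle counts of AXL, a receptor kinase, 105 of 108 of CAV1 and 32 of 33 of YAP1, against 11, 6 and 7 counts over the valemetostat libraries. Without vehicle replicate 3 the list had 32 members higher and the camera test gave adjusted p = 2.19e-12, against 4.73e-06 without vehicle replicate 2. PTGES, a prostaglandin synthase, rose from 0.0972 ± 0.0150 to 10.9 ± 1.06 CPM (edgeR adjusted p = 1.0e-08). TEAD2, a DNA-binding partner of YAP, went from 3 counts to 11.3 ± 0.854 CPM, a ratio of 428 with an interval of 146.2 to 2080, although it overlaps CD37 on the other strand. NOTCH1 and its target HES1 rose by 5.76 and 2.76 on the log2 scale, and CD44, an adhesion receptor, rose by 4.15. SLFN11, a helicase-like gene whose loss is linked to resistance to DNA-damaging drugs (ENSG00000172716.17, chromosome 17, 35350305 to 35373701), rose from 5.12 ± 0.370 to 31.6 ± 2.77 CPM (log2 fold change 2.63, edgeR adjusted p = 5.20e-08).

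Mesenchymal genes rose in 11 of 38 cases and fell in 3, the same counts adjusted over the list alone (median log2 fold change 0.35, camera adjusted p = 0.0241, and adjusted p = 0.682 with an estimated correlation). TNC, a matrix glycoprotein, rose from 0.156 ± 0.196 to 11.9 ± 1.67 CPM, and POSTN went from 1 count to 1.2 ± 0.28 CPM, a ratio of 142 with an interval of 25 to 5644. LOXL2, a collagen crosslinking enzyme, and the integrin gene ITGAV fell by 0.81 and by 0.61 on the log2 scale. Vehicle replicate 3 stood apart in this list as well, with 11 members at least 4-fold above both other vehicle libraries. VIM, an intermediate filament gene, measured 7.68 CPM there against 0.465 and 0.229 CPM in vehicle replicates 1 and 2. Without vehicle replicate 3 the list had 21 members higher and the camera test gave adjusted p = 7.50e-06, while it gave 0.0863 without vehicle replicate 1 and 0.0951 without vehicle replicate 2. Of 13 fibroblast and stromal markers tested among 20, 5 rose and 2 fell, the same counts adjusted over the list alone (median log2 fold change 0.28, camera adjusted p = 0.350). BGN, a matrix proteoglycan, rose from 0.484 ± 0.178 to 3.62 ± 0.747 CPM and COL3A1, a fibrillar collagen, fell from 5.36 ± 2.80 to 1.43 ± 0.0417 CPM. COL1A1 measured 12.4 CPM in vehicle replicate 3 against 0.552 and 0.601 CPM in the other vehicle libraries, and 8 markers rose without vehicle replicate 3, and 3 without valemetostat replicate 1 or 2.

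Epithelial genes rose in 14 of 29 cases and fell in 3, the same counts adjusted over the list alone (median log2 fold change 0.28, camera adjusted p = 0.0182, and adjusted p = 0.223 with an estimated correlation). KRT5, a basal keratin, rose from 0.0366 ± 0.0453 to 2.00 ± 0.555 CPM, and OVOL1, an epithelial transcription factor, from 0.796 ± 0.144 to 7.20 ± 0.923 CPM, while the splicing regulator ESRP1 fell from 239 ± 19.5 to 141 ± 4.20 CPM (edgeR adjusted p = 3.97e-05). Of 26 cancer-testis genes 11 rose and 8 fell, the same counts adjusted over the list alone (median log2 fold change 0.12, camera adjusted p = 0.402). GAGE1 went from 2 counts to 3.75 ± 0.461 CPM, a ratio of 211 with an interval of 57.9 to 1748, and PAGE1 rose from 0.518 ± 0.187 to 4.61 ± 0.751 CPM, while MAGEC1 fell by 0.43 on the log2 scale. Near-identical copies make single GAGE, MAGE and SSX genes uncertain, and 3 or 4 cancer-testis genes were lower, against 8, when vehicle replicate 1 or 3 or valemetostat replicate 1 or 2 was left out. Of 26 hematopoietic markers 11 were tested, of which 7 rose and 2 fell, the same counts adjusted over the list alone (median log2 fold change 3.16, camera adjusted p = 0.0239, and adjusted p = 0.309 with an estimated correlation). The set test gave 0.134 without a filter and 0.159 with a filter of at least 1 CPM in 3 libraries. The alpha globin genes HBA2 and HBA1, near-identical copies, rose from 0.0956 ± 0.0884 to 7.93 ± 1.67 CPM and from 0.335 ± 0.0318 to 9.45 ± 2.59 CPM. PTPRC, which encodes the leukocyte antigen CD45, and LCP1, a leukocyte actin bundler, fell by 1.54 and by 1.08 on the log2 scale.

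More genes of genome folding fell than rose, all but SMC2 by less than 2-fold. Of 34 CTCF, cohesin, condensin and related genes 15 fell and 2 rose, the same counts adjusted over the list alone (median log2 fold change -0.18, camera adjusted p = 0.00823, and adjusted p = 0.374 with an estimated correlation). SMC2, a condensin core subunit, fell from 256 ± 36.7 to 122 ± 3.02 CPM, and SATB1, a chromatin organiser, from 65.7 ± 1.25 to 41.6 ± 1.18 CPM (edgeR adjusted p = 1.76e-05 and 4.66e-05). The cohesin subunit STAG2 and the cohesin loader NIPBL fell by 0.38 and by 0.34 on the log2 scale, and LMNA, a nuclear lamina gene, and MAZ rose by 0.62 and 0.28. CTCF itself measured 97.7 ± 6.24 and 93.1 ± 1.30 CPM (edgeR adjusted p = 0.514). The count of fallen members was 8 without vehicle replicate 3 and 9 without valemetostat replicate 2, and that of risen members 1 without valemetostat replicate 1.

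Proliferation genes fell in 14 of 40 cases and rose in 1, the same counts adjusted over the list alone (median log2 fold change -0.17, camera adjusted p = 0.00527, and adjusted p = 0.414 with an estimated correlation). The replication genes MCM6 and CCNE2 fell from 391.7 ± 37.7 to 277 ± 6.06 CPM and from 122 ± 12.7 to 84.8 ± 5.69 CPM, CDC20, a mitotic activator, rose by 0.28 in log2 units, and MKI67 measured 437 ± 26.1 and 415 ± 21.8 CPM (edgeR adjusted p = 0.00115, 0.00126, 0.0203 and 0.531). Between 5 and 8 members fell when vehicle replicate 1 or 3 or valemetostat replicate 1 or 2 was left out, and CDC20 was not called without vehicle replicate 3 or valemetostat replicate 1. Of 30 cell cycle inhibitor and DNA damage genes 7 rose and 11 fell, the same counts adjusted over the list alone. Their median log2 fold change was -0.10 and their mean 0.36, and camera gave a downward direction (adjusted p = 0.417). GADD45B, a stress response gene, and SLFN13 rose by 4.09 and 3.99 on the log2 scale, and CDKN1C, a cell cycle inhibitor, by 1.72. The repair genes BRCA1 and BRCA2 fell, with log2 fold changes of -0.64 and -0.65. Of 31 apoptosis regulators 10 rose and 9 fell, or 12 and 9 adjusted over the list alone. Their median log2 fold change was 0.01 and their mean 0.35, and camera gave a downward direction with adjusted p = 0.921. RIPK3, a kinase of necroptosis, went from 1 count to 1.58 ± 0.596 CPM, a ratio of 169 with an interval of 29.8 to 6708, and BMF, a pro-apoptotic BCL2 family gene, rose from 4.4 ± 0.56 to 18 ± 1.8 CPM. CASP4, an inflammatory caspase, and BCL2, an anti-apoptotic gene, fell by 1.43 and by 0.48 on the log2 scale.

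The last 2 lists bear on RNA composition. Of 13 mitochondrially encoded mRNAs 3 rose and 0 fell, or 1 and 0 adjusted over the list alone (median log2 fold change 0.27, camera adjusted p = 0.162). MT-ND6 rose from 61.8 ± 14.9 to 101 ± 5.41 CPM and MT-ND1 from 3443 ± 155 to 4753 ± 928 CPM (edgeR adjusted p = 0.00604 and 0.0237). Mitochondrial genes took 8.98, 9.22 and 9.78% of the vehicle counts and 12.4, 13.5 and 9.03% of the valemetostat counts (exact two-sided permutation p = 0.3). Without valemetostat replicate 3, the library with the lowest share of its group, 11 members rose and camera gave adjusted p = 0.00193, while 1 rose without vehicle replicate 1 or 3 or valemetostat replicate 1 or 2. No member of this list fell by edgeR at an unadjusted p under 0.05, by DESeq2 or by limma-voom (0 in each). Of 40 ribosomal protein genes 4 rose and 0 fell by edgeR, the latter also at an unadjusted p under 0.05 and by the other 2 tools, or 0 and 0 adjusted over the list alone (median log2 fold change 0.08, camera adjusted p = 0.713). RPS19 rose from 445 ± 20.4 to 632 ± 105 CPM and RPS2 from 1184 ± 86.3 to 1510 ± 231 CPM (edgeR adjusted p = 0.00544 and 0.0376). Without valemetostat replicate 3, 1 ribosomal protein gene rose and 5 fell, and 1 rose without vehicle replicate 2 or 3. The calls of MT-ND1 and RPS2 were lost when 4 and 5 of the 6 libraries, respectively, were left out in turn.

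**Figure D2:**
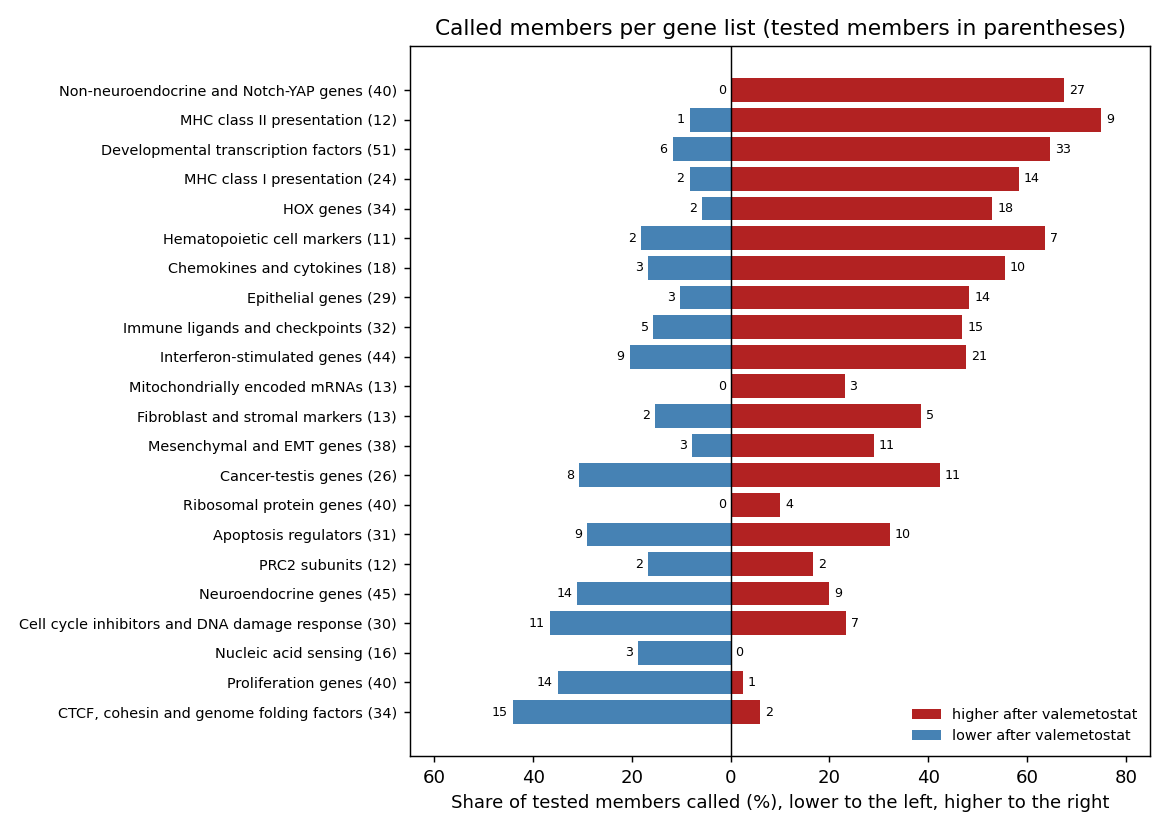
Share of tested members called higher (right) or lower (left) by edgeR at an adjusted p under 0.05, in percent, for each of the 22 gene lists, with the number of members called at each bar and the number tested in parentheses. The list of non-neuroendocrine and Notch-YAP genes had 27 of 40 members higher and none lower, and the CTCF and cohesin list 2 higher and 15 lower of 34.

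**Figure D3:**
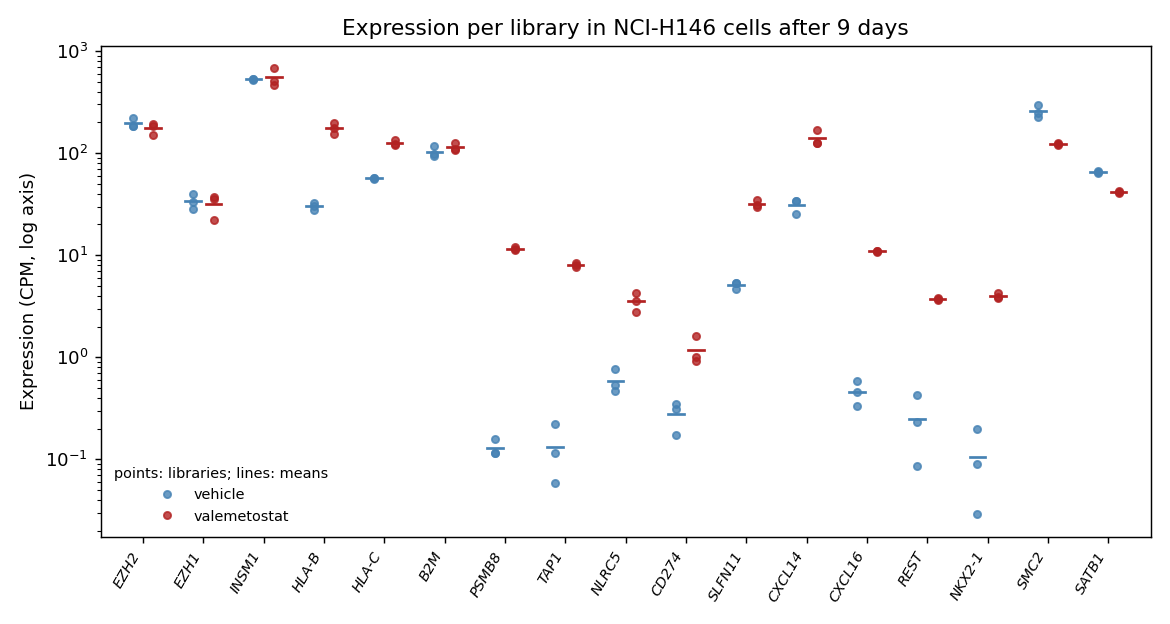
Expression in CPM on a log axis for 17 named genes, with a point per library, lines at the group means, vehicle in blue and valemetostat in red. HLA-B, PSMB8 and SLFN11 lay higher in all 3 valemetostat libraries than in all 3 vehicle libraries, while the groups overlapped for EZH1, INSM1 and B2M.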

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

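All alternatives were chosen before the data were examined except the fits without mitochondrially encoded genes and with protein-coding genes only and the counts of gene families without each library and within deciles of vehicle expression, which were chosen after seeing the data. The count of 7636 changed genes ranged from 5148 at an adjusted p under 0.01 to 8889 without a filter on low counts, and from 6274 without valemetostat replicate 2 to 7733 without vehicle replicate 2. Of the genes changed at least 2-fold, 0 changed sign in any fit with another scaling, filter or tool, with the replicate block or without a library. Their selection by fold in the same libraries makes a change of sign unlikely. Among those still tested, 176 lost significance without valemetostat replicate 3, the most in any of these fits. With DESeq2 174 lost it, a count that includes any genes to which DESeq2 gave no adjusted p. With at least 1 CPM in 3 libraries, where fewer genes were tested, 1648 of the 2468 genes higher at least 2-fold were shared. The median log2 fold change of all genes was 0.016 with TMM, 0.015 with DESeq2 size factors and 0.041 with library size only, and the higher share of changed genes was 56.9, 56.8 and 60%. The count of genes lower was 1901 at an adjusted p under 0.01, and that of genes lower at least 2-fold was 301 with at least 1 CPM in 3 libraries and 252 with protein-coding genes only, where fewer genes were tested. Without a filter, 2928 genes rose at least 2-fold from under 1 CPM in vehicle, and median vehicle CPM was 0.508, 40.0 and 0.148 for genes higher, lower and not called, where more low genes were tested. With each library left out in turn these medians ranged from 0.740 to 1.69, from 40.3 to 48.4 and from 12.3 to 15.3 CPM. Of 66 named genes tested and reported, 62 were called and 58 kept the call in every setting that tested them. The exceptions were MT-ND1, RPS2, IFIH1 and BLOC1S5-TXNDC5. CIITA, CD274 and POSTN did not reach 1 CPM in 3 libraries, so they had no value with that filter. In leave-one-out fits the adjusted p was 0.421 to 0.996 for EZH1 and 0.270 to 0.837 for INSM1, with the sign turned without valemetostat replicate 3 for both genes and without vehicle replicate 2 for EZH1. The replicate numbers were not taken as pairs, since the correlations of deviations of same-numbered libraries were -0.11, 0.09 and -0.01. With the replicate block 7169 genes changed, and members higher were 1 for PRC2 subunits, 2 for proliferation genes and 2 for ribosomal proteins, while members lower were 0 for MHC class I and 0 for MHC class II; the block moved no other list count past 1.5 times, no set test and no call of a named gene but that of IFIH1 (adjusted p = 0.0885). With library size only, members lower were 1 for MHC class I and 0 for MHC class II, and 1 nucleic acid sensing gene was higher. No list was past the threshold in camera with an estimated correlation, which gave adjusted p = 0.223 for HOX, MHC class I, chemokine, immune ligand and epithelial genes, 0.309 for MHC class II and hematopoietic genes, 0.326 for developmental factors, 0.374 for non-neuroendocrine and CTCF and cohesin genes, 0.401 for neuroendocrine, 0.414 for proliferation and 0.682 for mesenchymal genes. Fry's directional test gave 0.00581 for PRC2 subunits, 0.00912 for apoptosis regulators and 0.0631 for cell cycle inhibitors, all upward against camera's direction, and 0.00912 for cancer-testis, 5.57e-05 for interferon-stimulated and 0.0631 for mesenchymal genes. Its mixed test, which does not compare a list with other genes, gave 8.66e-06 for PRC2 subunits and apoptosis regulators, 4.72e-06 for cancer-testis genes, 3.61e-06 for cell cycle inhibitors and nucleic acid sensing, 3.07e-06 for interferon-stimulated genes and 3.64e-05 for fibroblast markers. With at least 1 CPM in 3 libraries camera gave 0.235 for chemokines, 0.159 for hematopoietic markers, 0.116 for neuroendocrine genes and 0.913 with the direction turned for apoptosis regulators. Without a filter it gave 0.134 for hematopoietic markers and 0.999 with the direction turned for ribosomal proteins. With each library left out, camera gave 7.50e-06 to 0.0951 for mesenchymal, 0.00193 to 0.491 for mitochondrial, 0.0256 to 0.0631 for neuroendocrine, 0.771 to 0.971 for apoptosis, 0.683 to 0.971 for nucleic acid sensing and 0.300 to 0.871 for ribosomal protein genes, with turned directions for the last 3. In the same fits members higher numbered 10 to 21 for mesenchymal, 3 to 8 for fibroblast, 1 to 11 for mitochondrial, 5 to 8 for neuroendocrine, 1 to 2 for CTCF and cohesin, 0 to 1 for proliferation, 0 to 1 for nucleic acid sensing, 1 to 3 for ribosomal protein genes and 1 for PRC2 subunits. Members lower numbered 8 to 16 for CTCF and cohesin, 5 to 17 for proliferation, 3 to 8 for cancer-testis, 1 to 2 for HOX, 0 to 2 for MHC class I, 0 for MHC class II, 1 to 3 for PRC2 subunits and 0 to 5 for ribosomal protein genes. Except where fewer or more genes were tested, the cause was not tested. Over all comparisons with an alternative, those given here included, 97 of 118 counts and baseline levels and 337 of 396 list counts stayed within 1.5 times, or within 1 SD for baseline levels, and 964 of 987 values of named genes and 285 of 330 set tests kept their direction and side of the threshold. Depth limits the folds of genes silent in vehicle, which are bounds or ratios with wide intervals.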

Other observations

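The comparisons of symbol roots and of single libraries in this part were chosen after the data were seen. The tests of explanations were set for patterns noticed in the fold changes, before the ratios and shuffles that decide them were computed. Counts of HBB and of blood cell markers in the fixed lists were already part of the list results by then. The tests of genomic span replaced a first version whose outcome was nearly fixed, before any shuffle was run. Several gene families, some with members in the fixed lists, held many risen genes. Among symbol roots with at least 10 tested genes, 12 of 16 mucin genes (MUC), 9 of 11 kallikrein peptidase genes (KLK), 12 of 27 keratin genes (KRT) and 15 of 39 collagen genes (COL) were higher by at least 2-fold, against 13.3% of all tested genes with a symbol (one-sided Fisher's exact test, adjusted p = 3.85e-06, 4.33e-05, 0.00354 and 0.00354). Genes silent in vehicle enter the test only where they rose, so families were also compared with tested genes of the same decile of vehicle expression. Chance then gave 7.36, 6.42, 11.3 and 13.3 risen members, and none of these families passed (one-sided exact test within deciles, adjusted p = 0.0646, 0.927, 1 and 1). The HLA root alone passed upward in that comparison, with 13 of 16 members higher against 6.86 by chance (adjusted p = 0.00897). The developmental roots HOXA, LHX and TBX held 7 of 14, 6 of 10 and 6 of 12 members higher by at least 2-fold. They passed against all genes (one-sided Fisher's exact test, adjusted p = 0.0251, 0.0202 and 0.0377) but not within deciles. Downward, LINC noncoding genes alone passed, with 38 of 390 lower by at least 2-fold against 12.9 by chance (adjusted p = 1.98e-07). More of the same 390 genes rose, 72 by at least 2-fold, or 18.5% against 13.3% of all tested genes with a symbol. Vehicle replicate 3 held 9 collagen genes at least 4-fold above both other vehicle libraries, and without it 23 of 40 collagen genes were higher by at least 2-fold. Members of a family share sequence and often a locus, so they are not independent.

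Genes that span long stretches of the genome were among the falls, named here after their values were seen. CSMD3, which spans 1214 kb, fell from 174 ± 13.2 to 33.7 ± 3.50 CPM, the microtubule-binding NAV3 from 41.3 ± 5.51 to 8.96 ± 0.190 CPM and the axon guidance receptor ROBO2 from 109 ± 7.41 to 53.0 ± 1.37 CPM (edgeR adjusted p = 4.90e-08, 2.01e-07 and 2.93e-06). RALYL, MGAT4C, a glycosyltransferase gene, DPYD, an enzyme gene of pyrimidine breakdown, CADM2 and FHIT had log2 fold changes of -1.74, -1.64, -1.43, -1.40 and -1.12. In valemetostat replicate 1 the immediate early genes EGR1 and FOS measured 85 and 30 CPM, against 2.18 and 2.31 CPM in replicate 2 and 1.96 and 2.06 CPM in replicate 3, and neither was called (edgeR adjusted p = 0.246 and 0.160). Vehicle replicate 3 had 47 tested genes at least 4-fold above both other vehicle libraries, among them COL1A1, COL6A1 and THBS1, where each of the other 5 libraries had between 2 and 8 genes that far above both others of its group. GREM1 had 574 counts in vehicle replicate 3 and 4 and 3 in the other vehicle libraries. Whether this library held other cells or came from another state of the culture was not tested and stays open. The vehicle means and SDs of mesenchymal, stromal, and non-neuroendocrine and Notch-YAP genes include this library.

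Transcripts typical of blood cells rose from near 0, among them IGHM, the immunoglobulin heavy chain mu constant region (chromosome 14, 105851705 to 105856218), from 0.0847 ± 0.0796 to 21.6 ± 1.09 CPM, and CD33, a myeloid surface receptor (chromosome 19, 51225064 to 51243860), from 0.0417 ± 0.0223 to 11.1 ± 3.15 CPM (edgeR adjusted p = 1.29e-08 and 7.99e-08). Cells of another type would bring their other abundant transcripts, but the median of 12 B cell transcripts reached at most 0.00593 of IGHM in a valemetostat library, that of 12 myeloid transcripts at most 0.00597 of CD33, and HBB at most 0.00208 of HBA1 and HBA2 together. IGKC had 11 counts over the valemetostat libraries, IGLC2 0, LYZ 11 and S100A8 3, CORO1A measured 21.0 and 23.1 CPM in the 2 groups, and 6 genes of each marker list were also in other lists. The marker genes CD37, CD74 and CYBB rose, to 0.542, 0.618 and 0.878 CPM (edgeR adjusted p = 5.30e-04, 0.0295 and 6.33e-05), and CD37 overlaps TEAD2 on the other strand. The medians and the HBB ratio argue against admixed B cells, myeloid cells and erythroid cells, and a candidate explanation, not tested beyond the comparison of the groups, is the opening of silent loci in the tumour cells by valemetostat.

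Genes that fell by at least 2-fold spanned long stretches of the genome, with a median of 49.5 kb over the 435 of 488 with a span, against 26.5 kb for 18487 tested genes and 22 kb for 2370 genes that rose. Above 500 kb were 30 of the fallen genes (6.90%), 38 of the risen genes (1.60%) and 1.51% of all. Shuffling the fallen label 10000 times within deciles of exonic length, GC content or vehicle expression left the observed median 2.35, 1.34 and 2.52 times the shuffled mean (one-sided permutation p = 1e-04, 2e-04 and 1e-04, where 1e-04 is the smallest that the shuffles can give). Each of these alone therefore leaves part of the pattern over, although the ratio was 1.87 without deciles, so part of it may go with the low GC content of the fallen genes, at a median of 42.6% against 48.6% for all. A share of unspliced RNA in total RNA libraries and a biological effect of valemetostat on long genes stay open, and neither was tested.

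Among tested genes, those that rose at least 2-fold lay next to each other more often than when shuffled. Genes removed by the filter were skipped, and a gene silent in vehicle was tested only where it had counts after valemetostat. There were 811 neighbouring pairs of risen genes, against a mean of 426 (range 358 to 484) in 10000 shuffles within deciles of vehicle expression, a ratio of 1.90. Without deciles the ratio was 2.67, so part of the excess goes with vehicle expression. The ratio was 1.83 without pairs that overlap or lie within 10 kb, and 1.898 without pairs of the same symbol root (one-sided permutation p = 1e-04 in each, the smallest that the shuffles can give). Low expression, shared reads of adjacent genes and families of the same symbol root thus each fail to account for the whole excess. Related neighbours with different roots, such as IGHD and IGHM, stayed in, so tandem families are only partly covered. Near pairs and pairs of the same root were not left out together. A hypothesis is that whole domains may be released from Polycomb silencing, which was not tested since chromatin data were not used here. The longest runs of risen neighbours held 12 genes at the immunoglobulin heavy chain locus on chromosome 14 (105526603 to 106288828), 11 genes from LIN7B to SLC17A7 on chromosome 19, and 9 genes each from KLK2 to KLK14 on chromosome 19, from TMPRSS6 to CDC42EP1 on chromosome 22 and from TSBP1-AS1 to HLA-DMA on chromosome 6. Another 4 runs held 7 genes, among them HOXC genes on chromosome 12 and GAGE genes on the X chromosome. A run is not an unbroken stretch of risen genes, since untested genes were passed over. The HOXC run passed over HOXC5 and HOXC12, with 6 and 12 counts after valemetostat. The run to HLA-DMA passed over HLA-DRA and HLA-DMB, with 6 and 27, among others.

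The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division gave 7636 changed genes with edgeR and was the 1 division with as many. The highest of the others gave 0, and these others gave between 44 and 1262 genes at an unadjusted p under 0.05. Each of the others mixes libraries of both treatments in each group, so the treatment difference widens the spread within groups. Their 0 is therefore no measure of how many genes chance would call.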
